A study of Drosophila melanogaster with 4 samples.

How the data were processed

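Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map HP1c in head nuclei of adult Oregon-R Drosophila melanogaster, a wild-type laboratory strain. HP1c is a member of the heterochromatin protein 1 family, chromatin proteins that carry a chromodomain. Per the labels' protocols, flies were raised in population cages, heads were separated from bodies with sieves, tissue was fixed with formaldehyde, and chromatin was sheared by sonication before precipitation. The series holds 4 samples in 2 groups, 2 HP1c ChIP libraries and 2 input libraries. Each input served as the control for the ChIP library of the same number, and no value of the inputs themselves was used here. The labels do not say that the 2 replicates came from separate fly collections, so SDs measure only the spread between these samples, which may be technical. The p-values come from positions, clusters, pairs or bins within these lists and do not measure spread between fly collections.

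Values were read from 3 lists of regions, 1 for each ChIP replicate and 1 for the replicate set, which combines the replicates. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Positions are on FlyBase release 5, per the file headers, which also give the sequence lengths used here. Each region carries a signed score deposited by the authors, whose scale is not given in the sources used here. Every region named enriched scored above 0 and every region named depleted scored below 0. The region caller, its threshold and the way the replicates were combined are not given in the sources used here. Scores were used to describe, rank or filter clusters within a list and to correlate overlapping clusters. They were not read as fold enrichment. The lists carry no read counts, so the depth of each library is unknown, and binomial intervals on shares of clusters cover only the number of clusters.

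Enriched regions are called clusters below. Overlap meant sharing at least 1 bp. The share of overlapping clusters was compared with 1000 circular shifts of one list, in which the clusters of each sequence moved together by a random offset, and the permutation test was one-sided. The same test was planned for the replicate set, but its overlap with its own replicates follows from how it was made, so only the shares are given. Scores were correlated over best-overlap pairs, 1 partner per cluster of replicate 1, with two-sided permutation tests of 100000 resamples. These correlations run across clusters, which are not independent replicates. Cluster density on chromosome 4 was compared with the share of length of 6 sequences (X, 2L, 2R, 3L, 3R and 4) by a two-sided exact binomial test in each replicate. The same test compared the 6 Het scaffolds and U, the sequences of heterochromatin and unplaced sequence, with their share of the 13 sequences that hold clusters. Clusters lie near one another and scaffold lengths include sequence to which reads map poorly, so these p-values are too small where densities differ. Poorly mapped sequence can also lower the density ratio of the scaffolds itself. Percentages of clusters carry exact (Clopper-Pearson) 95% intervals, and other intervals are bootstrap intervals of 1000 resamples.

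The tests of overlap, of rank correlation, of chromosome 4 and of the Het scaffolds and U, the groups, most alternatives to these tests and the rule for named regions were fixed before the data were examined. The rule took the 10 highest-scoring clusters of the replicate set that overlap a cluster in both replicates, the 3 widest clusters, and the highest-scoring cluster of each sequence. Comparisons added after seeing the data were X against the other large arms in bins of 1 Mb (permutation test over bins), the centromere-proximal 1 Mb of each large arm (exact binomial test), spacing of clusters against 1000 random placements on the same sequence, score ranks on chromosome 4, score ranks and widths of clusters found in 1 replicate alone, Pearson correlation, correlation of counts per bin, scores of wide replicate-set clusters, and overlap of depleted regions with clusters of either replicate (circular shifts). Alternatives added then were those of these comparisons, the length of Uextra, and cluster numbers without each replicate. In all, alternatives included stricter score limits, a larger overlap, merging of clusters within 500 bp, a random-placement null, base pairs in place of cluster numbers, and omission of each replicate.

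The gene table used here describes Release 6 of the genome, a different build, so none of its coordinates were used. Shares of clusters at promoters, genes with a cluster at the start site, the 27 gene lists and start-site motifs were planned and were not analysed here. Clusters are therefore named by position alone.

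Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap test was tested on simulated data of 3000 clusters per list. Of 50 pairs of unrelated lists, 1 had a p-value under 0.05, and all 50 pairs built with a known shared part did. An X density ratio of 1.3 was recovered as 1.30 ± 0.0328 (SD over 50 simulations of 6000 clusters). Simulated clusters were placed independently, whereas the real ones lie near one another. These simulations therefore check the computation only, and this SD does not measure the precision of the real ratio.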

Results

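HP1c was mapped by ChIP-seq in adult head nuclei with 2 ChIP libraries, each called against the input library of the same number. The design holds 1 antibody, 1 tissue and 1 strain, so the comparisons are between the replicates, between chromosomes, and between each replicate and the combined replicate set.

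HP1c clusters were numerous and of similar number and width in both libraries. Replicate 1 held 6008 clusters over 15.95 Mb and replicate 2 held 5764 clusters over 15.37 Mb, a mean of 5886 ± 173 clusters (SD, n = 2). They covered 11.2% ± 0.297 (SD, n = 2) of the 13 sequences that hold clusters. The median cluster was 2271 bp wide in replicate 1 and 2283 bp wide in replicate 2, and the narrowest was 1301 bp in both. The widest reached 19313 bp and 21402 bp. The authors' score had a median of 0.950 in replicate 1 and 1.12 in replicate 2. Wider clusters scored higher within each list, with a rank correlation of 0.748 in replicate 1 and 0.764 in replicate 2.

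The first comparison asked whether the 2 libraries marked the same regions. Of the clusters of replicate 1, 86.5% (95% interval 85.6 to 87.3) overlapped a cluster of replicate 2, and 90.1% (89.3 to 90.9) of those of replicate 2 overlapped replicate 1. Shifted positions gave 23.0% and 23.9%, so the overlap was 3.76-fold and 3.77-fold that of shifted lists (permutation p = 0.001 for each, the smallest that 1000 shifts can give). This ratio depended on the rule: it was 6.93 and 6.94 when 50% of the cluster had to overlap, 10.0 in both directions with reciprocal overlap of 50%, and 6.00 and 6.02 in the upper 50% by score. The lists shared 13.6 Mb, or 76.3% of the base pairs in either. In the 4899 pairs in which each cluster met exactly 1 partner, starts differed by a median of 65 bp and ends by 63 bp.

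Clusters found in 1 replicate alone had lower scores than shared ones. In replicate 1, 60.5% of the 25% of clusters with the lowest scores overlapped replicate 2, against 99.8% of the 25% with the highest. In replicate 2 the shares were 72.4% and 99.9%. The 814 clusters unique to replicate 1 had a median width of 1695 bp, against 2389 bp for the 5194 shared ones, and their mean percentile of score lay 37.2 points lower (permutation p = 1e-05). The 571 clusters unique to replicate 2 were 1792 bp wide, against 2346 bp, and lay 34.1 points lower (permutation p = 1e-05). Both p-values are the smallest that the permutations can give.

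**Figure D1:**
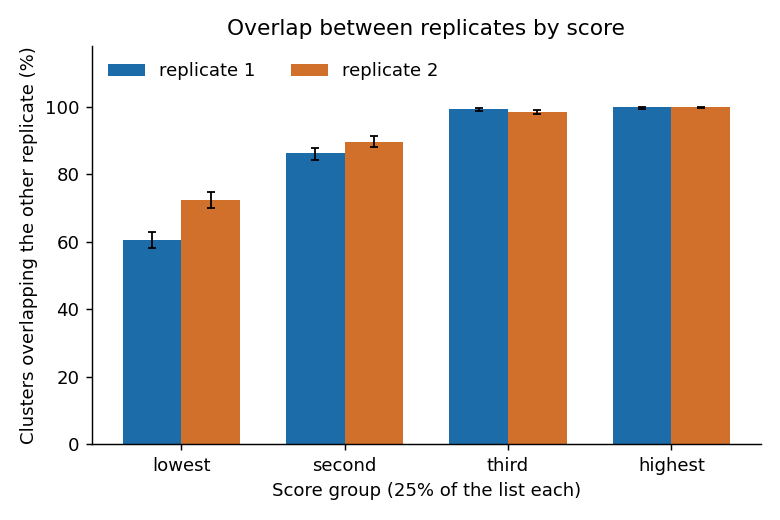
Share of clusters that overlap a cluster of the other replicate (%), by score, in groups of 25% of each list from lowest to highest; bars are the shares in replicate 1 and replicate 2 and error bars are exact 95% intervals. The lowest groups reach 60.5% and 72.4%, and the highest 99.8% and 99.9%.

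Scores of overlapping clusters rose together. Over 5194 pairs Spearman's rho was 0.878 and Pearson's r was 0.898 (permutation p = 1e-05 for each, the smallest the permutations can give). Of the 100 highest-scoring clusters of replicate 1, 64 overlapped 1 of the 100 highest of replicate 2, and all 100 overlapped some cluster of it. The number of clusters per 1 Mb bin also ran in parallel over 117 bins of the large arms, with Pearson's r of 0.953 and Spearman's rho of 0.954 (permutation p = 1e-05 for each).

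**Figure D2:**
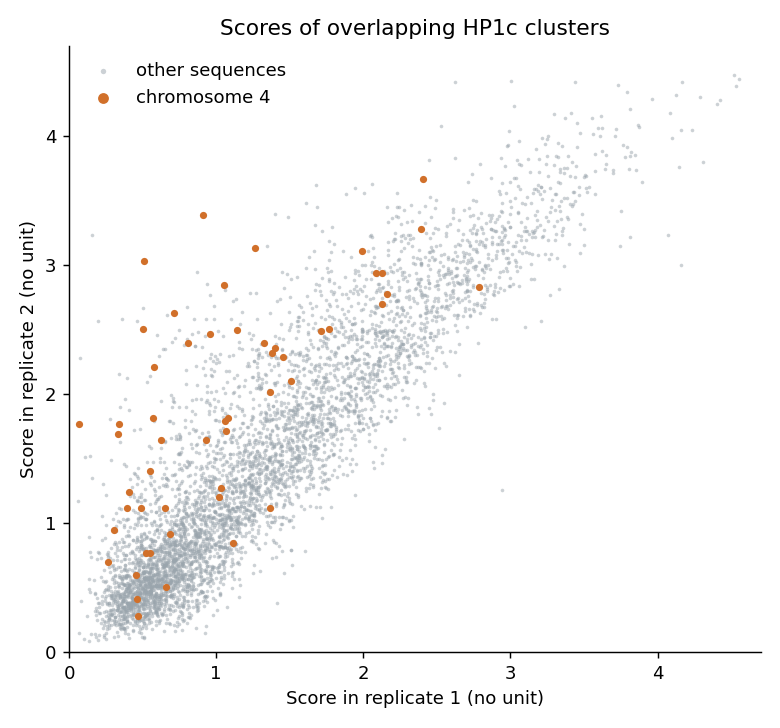
Score in replicate 1 (horizontal axis, no unit) against score in replicate 2 (vertical axis, no unit) for 5194 pairs of overlapping clusters; each point is a pair and the 53 pairs on chromosome 4 are coloured. Scores rise together (rho = 0.878), and most chromosome 4 points lie toward higher values in replicate 2. Scores of shared clusters were higher in replicate 2 in general (medians of 1.11 in replicate 1 and 1.28 in replicate 2), which the plot does not remove.

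The 10 strongest clusters lay on chromosomes 2 and 3, and each overlapped a single cluster in both libraries. The highest-scoring cluster of the replicate set lay on 2R from 2548453 to 2552433, with a score of 4.51, and ranked 1 in replicate 1 and 2 in replicate 2. Next came 3L from 15974845 to 15977342 (score 4.48), which ranked 3 and 1, and 3R from 3732017 to 3734459 (4.46), which ranked 2 and 8. The 2L arm held 3 of the 10, at 7798706 to 7801547 (4.34), 8996317 to 8998714 (4.29) and 18687704 to 18690749 (4.20). A further cluster on 2R ran from 19410011 to 19412490 (4.31). The others were on 3L, at 21720574 to 21723069 (4.32), 16579209 to 16582769 (4.14) and 2261554 to 2264008 (4.12). Their widths ran from 2398 to 3981 bp, above the replicate-set median of 2248 bp. No X cluster was among these 10, and the highest on X, from 2596776 to 2599701, scored 3.87 and ranked 21 in the replicate set.

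The 3 widest clusters scored above the upper quartile of the replicate set (1.62) and below the 10 strongest. The widest ran on X from 7584505 to 7605982, over 21478 bp, with a score of 2.15. Replicate 2 held it as 1 cluster of 21402 bp, whereas 3 clusters of replicate 1 lay in it. The next ran on 2R from 17583455 to 17602759 over 19305 bp (score 2.26), and another on X from 8779974 to 8796741 over 16768 bp (1.99). Of the 38 replicate-set clusters wider than 10 kb, 15 were on X, which held 1617 of all 7116 clusters of that list. In replicate 1, 9 of 19 clusters this wide were on X, and in replicate 2, 6 of 15. No test was made of these counts.

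The next comparison was between chromosomes. Chromosome 4, a small autosome rich in heterochromatin, carried clusters at the density of the large arms. It held 45.9 clusters per Mb in replicate 1 and 46.6 in replicate 2, a mean of 46.2 ± 0.523 (SD, n = 2). Its density was 0.933 and 0.991 times that of the other 5 arms (exact binomial p = 0.665 and p = 1). With only 62 and 63 clusters on chromosome 4, these tests could not exclude a modest difference. Measured by covered base pairs, the ratio was 1.01 in replicate 1 and 1.38 in replicate 2, so the replicates differed in width there. Clusters of chromosome 4 had a median width of 2294 bp in replicate 1 and 3321 bp in replicate 2. Its highest-scoring cluster, from 978074 to 981971, scored 3.13 in the replicate set and ranked 613 in replicate 1 and 103 in replicate 2.

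The Het scaffolds and U carried few clusters. They held 95 clusters in replicate 1 and 102 in replicate 2, or 1.58% and 1.77% of all, on 13.8% of the length. Their density was 0.100 and 0.112 times that of the rest (exact binomial p = 1.05e-253 and p = 5.27e-233). Reads map poorly to part of this sequence, and mappability was not tested. The ratios therefore describe called clusters per length and cannot show how scarce HP1c is there. These lengths leave out Uextra, a header sequence of 29.0 Mb on which no cluster was called, and counting it lowered the ratios to 0.0400 and 0.0449. XHet stood above the other scaffolds with 4 and 8 clusters, 19.6 and 39.2 per Mb, on 0.204 Mb. U held 2.99 and 3.38 per Mb. Those that were called did not score low, with a median of 1.00 in replicate 1 and 1.51 in replicate 2 over all of these scaffolds. The highest-scoring replicate-set cluster was at 30711 to 35929 on 2LHet, 1822766 to 1826606 on 3RHet, 83280 to 85918 on XHet and 304288 to 306316 on YHet, and each overlapped a cluster in both replicates. Those of 2RHet (2832608 to 2833790), 3LHet (678009 to 679022) and U (1689488 to 1690488) overlapped none in either. These were 1183, 1014 and 1001 bp wide, narrower than the narrowest cluster of either replicate (1301 bp).

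The X chromosome was the densest of the large arms. It held 58.4 ± 1.73 clusters per Mb (SD, n = 2), against 42.8 ± 1.23 on 2L, 49.6 ± 2.24 on 2R, 45.6 ± 0.346 on 3L and 45.2 ± 1.98 on 3R. This comparison was chosen after seeing the data. In replicate 1, bins of 1 Mb on X held 60.1 ± 14.7 clusters (SD over 22 bins). The 95 autosomal bins held 46.9 ± 13.3 (permutation test over bins, p = 8e-05). In replicate 2, bins on X held 57.6 ± 15.3 against 44.9 ± 13.1 (permutation test over bins, p = 0.00011). The whole-arm density ratio was 1.28 in each replicate. Bins lie side by side on the same arms and are not independent, so these p-values may be too small. Clusters covered 16.3% ± 0.562 of X, 13.1% ± 0.577 of 2R, 11.7% ± 0.500 of 3R, 11.6% ± 0.219 of 3L and 11.5% ± 0.178 of 2L (SD, n = 2). Chromosome 4 was covered to 13.2% in replicate 1 and 17.2% in replicate 2, where it exceeded the 15.9% of X.

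**Figure D3:**
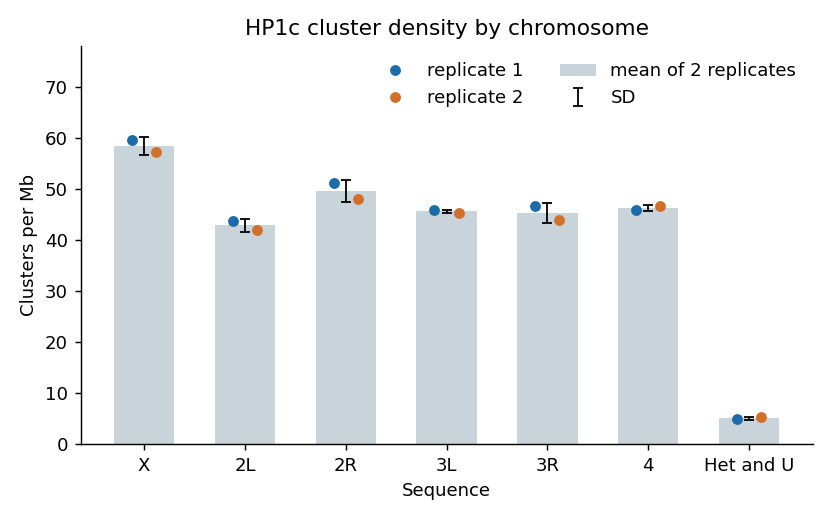
Clusters per Mb (vertical axis) on each large arm, on chromosome 4 and on the Het scaffolds and U together; bars are the mean of 2 replicates, error bars the SD, and points the replicates. X has 58.4 per Mb, chromosome 4 has 46.2, and the Het scaffolds and U have 5.10.

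The bin nearest the centromere held fewer clusters than the mean of the other bins on 4 of the 5 large arms, a comparison chosen after seeing the data. The centromere-proximal 1 Mb of 3L held 6 and 9 clusters in replicates 1 and 2, that of X 21 and 20, that of 2R 25 and 24, and that of 2L 32 and 26. On 3R it held 50 and 47, above the mean of 46.7 and 44.0 in the other bins of that arm. Together these stretches had 0.535 and 0.525 times the density of the rest of the arms (exact binomial p = 3.1e-15 and p = 2.87e-15). Clusters lie near one another and the 5 stretches differ, so these p-values are too small. Mappability of these stretches was not tested, and poorly mapped sequence can lower the ratio itself. The densest bin by the mean of both replicates, on X from 12422828 to 13422827, held 81 and 84 clusters, although in replicate 1 the bin on X from 5422828 to 6422827 held more (85, against 72 in replicate 2). On 2L, the bin from 15011545 to 16011544 held 17 and 18, fewer than the 32 and 26 of the proximal bin, which was not the lowest of that arm.

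**Figure D4:**
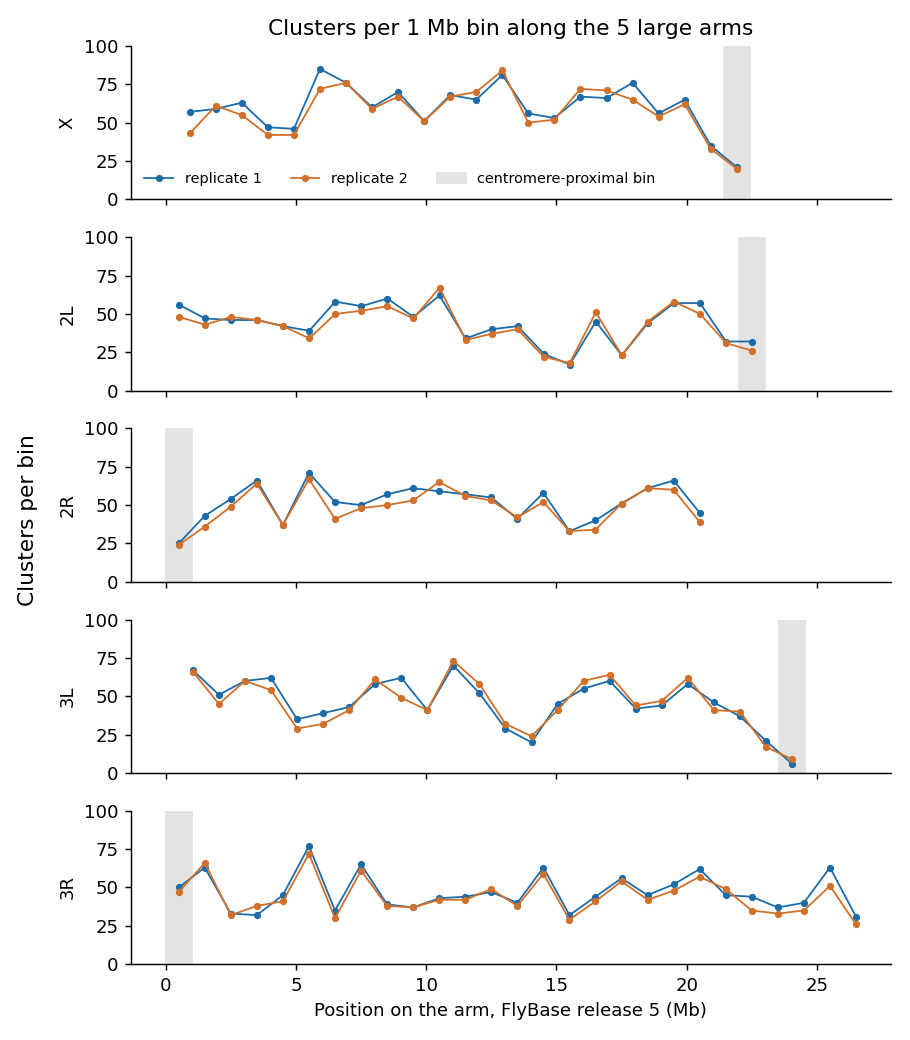
Number of clusters per 1 Mb bin (vertical axis) along X, 2L, 2R, 3L and 3R (horizontal axis, Mb on FlyBase release 5); lines are replicate 1 and replicate 2, and grey marks the centromere-proximal bin. Both lines follow each other along each arm. The proximal bin held fewer clusters than the mean of the other bins on X, 2L, 2R and 3L, with 6 and 9 on 3L. It did not on 3R, with 50 and 47.

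Clusters lay close to one another more often than random placement gives, in a comparison also chosen after seeing the data. On the large arms, 63.2% of the clusters of replicate 1 and 62.6% of those of replicate 2 had a neighbour within 5 kb. Random placement on the same arm gave 43.5% and 41.9% (permutation p = 0.001 for each, the smallest that 1000 placements can give). The median gap between clusters was 7020 bp in replicate 1 and 7438 bp in replicate 2.

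The last comparison set the combined list against its replicates. The replicate set held 7116 clusters over 18.8 Mb and took in 99.2% of the clusters of replicate 1 and 99.0% of those of replicate 2. In the other direction, 81.9% of its clusters overlapped replicate 1 and 78.6% overlapped replicate 2. Both replicates were overlapped by 5072 of its clusters, replicate 1 alone by 756, replicate 2 alone by 518, and neither by 770. The clusters found in both were wide and high in score, with a median of 2510 bp and a score of 1.17. Those found in replicate 1 alone had a median score of 0.279, those in replicate 2 alone 0.297, and those in neither 0.347 with a median width of 1264 bp. This list is the authors' own combination and not a further replicate, so these shares describe how it was made and are given without a test.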

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

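The replicate set names 15 regions as depleted, which none of the comparisons above uses. Replicate 1 names 2 such regions and replicate 2 names 1. Their scores in the replicate set ran from -0.204 to -0.000673, and the next lowest after the first was -0.0514. None of the 15 overlapped a depleted region of either replicate. Of the 15, 11 overlapped an enriched cluster of at least 1 replicate, 5 of replicate 1 and 8 of replicate 2. That is 73.3%, against 21.3% for shifted positions (one-sided permutation p = 0.001, the smallest that 1000 shifts can give), in a test chosen after the counts were seen. The replicate set combines the same libraries, so its regions are not independent of these clusters. Shifted positions ignore that tie, so no conclusion is drawn from the test. The 2 depleted regions of replicate 1 both overlapped an enriched cluster of replicate 2. The lowest score belonged to 3L from 12734085 to 12735762.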

How the results depend on the processing

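Of 75 alternatives over 20 results, 69 kept the direction and the side of the threshold or, for counts, stayed within 1.5 times the main value. These include the replicate set against shifted positions, where the outcome follows from how that list was made. Each overlap was counted as 2 results, a share and its ratio to shifted positions, which carry the same label. Leaving out a replicate only restates the value of the other. The 69 are therefore not separate checks. The remaining 6 have no test and moved beyond that bound, or by more than the SD between replicates. The mean number of clusters went from 5886 to 2943 for the upper 50% by score, to 1472 for the top 25% and to 2947 without clusters narrower than the median, which follows from how those subsets are made. Counting base pairs moved the chromosome 4 ratio from 0.962 to 1.20, the ratio for the Het scaffolds and U from 0.106 to 0.119 and the proximal ratio from 0.530 to 0.614, which means wider clusters on average there, since a ratio of base pairs is the ratio of counts times that of mean widths. The last 2 stayed below 1, and the first passed from below to above 1. Without each replicate, the values ran from 5764 to 6008 clusters, from 0.933 to 0.991 for chromosome 4, from 0.100 to 0.112 for the Het scaffolds and U, from 1.276 to 1.279 for X, from 0.525 to 0.535 for the proximal stretches and from 1.45 to 1.49 for spacing. Overlap between replicates stayed between 83.1% and 90.6% while its ratio to shifted positions rose to 10.0 with reciprocal overlap of 50%. In the upper 50% by score, the chromosome 4 ratio was 0.843 in replicate 1 and 1.11 in replicate 2. The length of Uextra, counted as an added choice, lowered the ratio for the Het scaffolds and U to 0.0424. Alternatives added after seeing the data were those of X, the proximal stretches, spacing and chromosome 4 ranks, the Uextra length, and cluster numbers without each replicate. No paired analysis was possible because the input libraries have no values of their own here. Promoter share, genes with a cluster at the start site, gene list enrichment and start site motifs were not run, nor were their alternatives. Depth is unknown and its effect could not be examined.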

Other observations

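Of the tests below, only that of X density among shared clusters had its outcome written down before its result was seen. The others were chosen or worded after related values had been seen. The design names no groups that differ in biology, so no biological explanation was tested.

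Of the replicate-set clusters in the top 25% by score, 13 overlapped neither replicate. Of these 13, 9 were on the Het scaffolds or U and 9 were narrower than 1301 bp. Among all 770 clusters found in neither replicate, 4.94% were on the Het scaffolds or U, against 2.11% of the whole replicate set.

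The X chromosome had 1.28 times the cluster density of the autosomal arms in each replicate. If weak calls near the threshold made the excess, it would shrink among strong clusters, but in the upper 50% by score the lower of the replicates' ratios was 1.35 (95% interval 1.18 to 1.56). Splitting of broad regions is argued against by a ratio of 1.25 (1.11 to 1.40) once clusters within 500 bp were merged. Among shared clusters the lower ratio was 1.27 (1.12 to 1.42), so the excess remained without calls made in 1 replicate alone. Shared clusters were 86.5% and 90.1% of the lists, so this ratio could move little from that of all clusters and is a weak test. Gene content of X, its copy number in flies of both sexes and its mappability were not tested and stay open.

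Chromosome 4 clusters may rank higher in replicate 2 than in replicate 1. Over all chromosome 4 clusters, the median percentile of score was 43.1 in replicate 1 and 58.7 in replicate 2, a difference of 15.6 points whose interval from -5.98 to 38.4 did not decide, and the paired tests that follow replaced this one after it was seen. Ranked over the same 5194 pairs in each list, which removes any rise of scores throughout a list, the 53 pairs of chromosome 4 stood 23.1 points higher in replicate 2 (95% interval 17.2 to 29.3; permutation p = 1e-05, adjusted p = 2.33e-05 over 7 comparisons), in 47 of 53 pairs, which argues against different clusters having been called as the whole cause. A wide cluster of replicate 2 can enter several of the 53 pairs, which the interval and p-value ignore. The 42 pairs of exactly 1 cluster each gave 20.2 points (14.1 to 26.6). Pairs with reciprocal overlap of 50% gave 21.4 points but leave width free. Pairs whose widths differed by at most 10% were therefore used in their place. These 13 rose by 14.3 points (8.12 to 22.3), so width cannot account for all of the rise, although part of it may come from width. The rise was not confined to chromosome 4 by the same permutation test. Pairs on the Het scaffolds and U stood 12.7 points higher (8.20 to 17.5, adjusted permutation p = 2.33e-05), in 60 of 78 pairs. Those on 2L stood 1.74 points higher on average (0.838 to 2.72, adjusted permutation p = 0.000158), but only 433 of 875 pairs rose. Those on X changed by -2.65 points (-3.44 to -1.88, adjusted permutation p = 2.33e-05), and 426 of 1153 pairs rose. The arms 2R, 3L and 3R did not pass. Both lists are ranked over the same pairs, so a rise on some sequences forces a fall on others. A difference between the libraries in antibody, fixation or input was not tested.

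The replicate set held 770 clusters found in neither replicate. A shorter minimum length in that list may account for part of them, since 54.8% (95% interval 51.2 to 58.4) were narrower than the narrowest replicate cluster, but not for the other 348. Weak regions that pass only when the replicates are combined stay open: of those 348, 97.4% (95.1 to 98.8) scored below the replicate-set median, but so did 98.8% and 97.0% of clusters as wide found in replicate 1 or replicate 2 alone. Median scores of these wide clusters were 0.278 for neither replicate, 0.273 for replicate 1 alone and 0.286 for replicate 2 alone.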
